A study of Homo sapiens with 2 samples.

How the data were processed

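Total RNA from SW48 cells was measured on whole-transcript GeneChip arrays, with 1 array for cells given the control siRNA and 1 for cells given the siRNA against YY1, at 5 nmol/L and 3 days of culture. Per the labels' protocols, siRNAs were transfected with a lipid reagent, RNA was isolated on columns, and fragmented sense cDNA was labelled with biotin by terminal transferase. Groups were taken from the sample titles.

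The authors deposited 1 summarized value per probe set, called a probe here, and these values were used as log2 values. The unit was read from the values themselves, which ran from 2.46 to 17.90 in siControl and from 2.32 to 17.97 in siYY1. The software, background correction, normalization and log base are not given in the sources used here. The sorted values of the arrays differed by at most 0.153, so they had been brought to nearly the same distribution before deposit. Values above 16, the log2 ceiling of a 16-bit scanner, occurred at 112 probes in siControl and 107 in siYY1. How such values arose is not given in the sources used here and was not tested. Every fold printed takes the values as plain log2, and would be larger or smaller under another base or a rescaling that stretched or compressed them.

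Probes were named through GEO's annotation of the array platform and through the Entrez identifiers of a RefSeq gene table of assembly GRCh38.p14, used only for symbols, synonyms, gene types and gene spans. Of 21448 probes, 17709 had 1 gene symbol, 0 had several and 3739 had none in the table used, and these last are unnamed here. The update changed 0 symbols. Where a gene had several probes (20 genes), their log2 values were averaged. No probe named YY1 was in the table used, so the level of YY1, planned as the first result, is not reported here.

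Genes were kept when their mean log2 value over both arrays was at or above the median of all named genes (7.54), which left 8844. A kept gene could still lie under this value on either array, where values were not shown to be above background. The size of its difference is then uncertain. No test was possible with 1 array per group, and no p-value was made from genes. Fixed rules of size took the place of tests, the main one being a difference of at least 1.5-fold between the arrays. The number of arrays limits the precision of every value. The genes named in the text followed a rule. It took the 14 kept genes with the largest positive and the 14 with the largest negative difference, leaving out small and noncoding RNA classes, open reading frame symbols without a name, olfactory receptors, immunoglobulin and T cell receptor segments and sex-specific genes. It added, for each list described, up to 2 kept members at each end, and ACTB and GAPDH as reference genes. Genes named outside this rule are marked as chosen after their values were seen.

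For gene lists, the median difference of the kept members was placed among 10000 random lists of the same size, drawn from the kept genes and matched on mean expression in 20 bins. A list needed 5 kept members. It was called apart from random lists when its percentile was under 2.5 or above the mirror of that value. Of 50 lists, 44 could be placed and 6 had too few kept members. To see how many lists chance could set apart, the differences were shuffled among genes of similar expression 1000 times. The design, the lists, the rules and most alternatives were chosen before the data were examined.

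The steps were tested on simulated data for the comparison of siYY1 with siControl, with 8844 genes of which 200 were changed by known amounts. The rule of 1.5-fold found 90% of the 100 genes changed 2-fold, 100% of the 100 genes changed 4-fold, and 4.69% of the unchanged genes. Of 10 lists of 30 genes shifted by 0.3, the list rule found 10, and it called 0 of 20 lists left unshifted. A shift of 0.3 exceeds most of the list medians reported below, and recovery of smaller shifts was not tested. These rates hold for the scatter given to the simulated genes, which 1 array per group cannot check.

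The alternatives were other fold thresholds, no filter or a stricter filter on dim genes, quantile normalization, median centring and lowess centring of the differences (fraction 0.3), the brightest probe of each gene, and random lists not matched on expression. Chosen after seeing the data were a filter on the brighter of the arrays and random lists matched on gene span as well. The latter used 5 bins of expression and 5 of gene span, so its expression matching was coarser than in the main setting. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.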

Results

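Gene expression was measured in SW48, an established human colorectal cancer cell line, 3 days after transfection with a small interfering RNA (siRNA) against YY1 or with a negative control siRNA. Each siRNA was used at 5 nmol/L. YY1 is a zinc finger transcription factor that can activate or repress its target genes. Total RNA from each culture was hybridised to a whole-transcript GeneChip, giving 1 array for the control (siControl) and 1 array for the knockdown (siYY1). The deposited log2 values covered 21448 probes, of which 17709 carried a gene name, for 17687 genes. The median log2 value over all probes was 7.11 in siControl and 7.10 in siYY1. Pearson's r between the arrays over probes was 0.995. Probes are not independent replicates, so this correlation describes how similar the arrays were and tests nothing.

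The comparison asked which genes differed in expression after knockdown of YY1. With 1 array per group there was no replicate error, no test was possible, and none of the differences below has a replicate check. All differences are siYY1 minus siControl on the log2 scale, and they describe these arrays. The level of YY1 itself was not analysed here, so the size of the knockdown and the labels of the arrays were not checked.

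The glucose transporter gene SLC2A3 stood far above all other genes kept, at 9.02 in siControl and 12.56 in siYY1, a difference of 3.54 or 11.7-fold. This was 3.50 times the next largest ratio. In the other direction, the tetraspanin gene TSPAN8 was 3.36-fold lower, the tight junction claudin gene CLDN4 2.82-fold lower and CEACAM5, which encodes carcinoembryonic antigen, 2.60-fold lower. In all, 33 of the 8844 genes kept by the expression filter were at least 2-fold higher in siYY1 and 51 were at least 2-fold lower.

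Among the other 13 genes with the largest positive differences, TXNIP, an arrestin-related protein that restrains glucose uptake, went from 10.08 to 11.82 (difference 1.74, 3.33-fold). Its paralog ARRDC4 was 2.52-fold higher, from 8.12 to 9.45. SLC2A14, a near-identical copy of SLC2A3, went from 11.49 to 13.19, a difference of 1.70. Because the probes of these copies may not separate them, the values of both SLC2A3 and SLC2A14 are uncertain. PGM2L1, which makes the sugar bisphosphate glucose 1,6-bisphosphate, was 2.42-fold higher (7.17 to 8.45). CCN1, a secreted matrix protein, was 3.25-fold higher (8.13 to 9.83), and DESI2, a putative isopeptidase, was 3.21-fold higher (10.94 to 12.62). CAB39L, a paralog of the LKB1 kinase scaffold CAB39, was 2.90-fold higher (6.99 to 8.53). RASSF5, a Ras effector, was 2.57-fold higher (7.02 to 8.38), and the histone acetyltransferase gene KAT2B 2.45-fold higher (7.46 to 8.75). SMIM15 (2.55-fold), MPZL3 (2.36-fold), ARHGAP31 (2.32-fold) and LRRC49 (2.29-fold) completed the 14 genes. In siControl, PGM2L1, CAB39L, RASSF5, KAT2B and LRRC49 (7.22) lay under the filter value of 7.54, which applied to the mean of both arrays. Their siControl values were not shown to be above background, so these folds are uncertain.

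Among the 14 genes with the largest negative differences, TSPAN8 went from 10.19 to 8.44 (difference -1.75) and a related tetraspanin gene, TSPAN1, from 10.30 to 8.75 (difference -1.55). CLDN4 went from 12.36 to 10.86, and CEACAM5 from 13.80 to 12.42. The integrin gene ITGB8 was 2.76-fold lower. The surface glycoprotein gene CD24 and the kallikrein-related protease gene KLK11 each had a difference of -1.32. NGEF was 2.88-fold lower. TRIAP1, a p53-induced inhibitor of apoptosis that takes part in mitochondrial lipid transfer, was 2.63-fold lower, and UQCC3, an assembly factor of respiratory complex III, 2.32-fold lower. GATD1 was 2.49-fold lower and the imprinted gene MEST 2.34-fold lower. The alpha-globin genes HBA1 and HBA2 had the same difference of -1.86. They are near-identical copies, so their values may not be separate measurements. In siYY1, KLK11 (7.53) and HBA2 (7.37) lay under the filter value of 7.54. These values were not shown to be above background, so the sizes of both differences are uncertain.

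**Figure D1:**
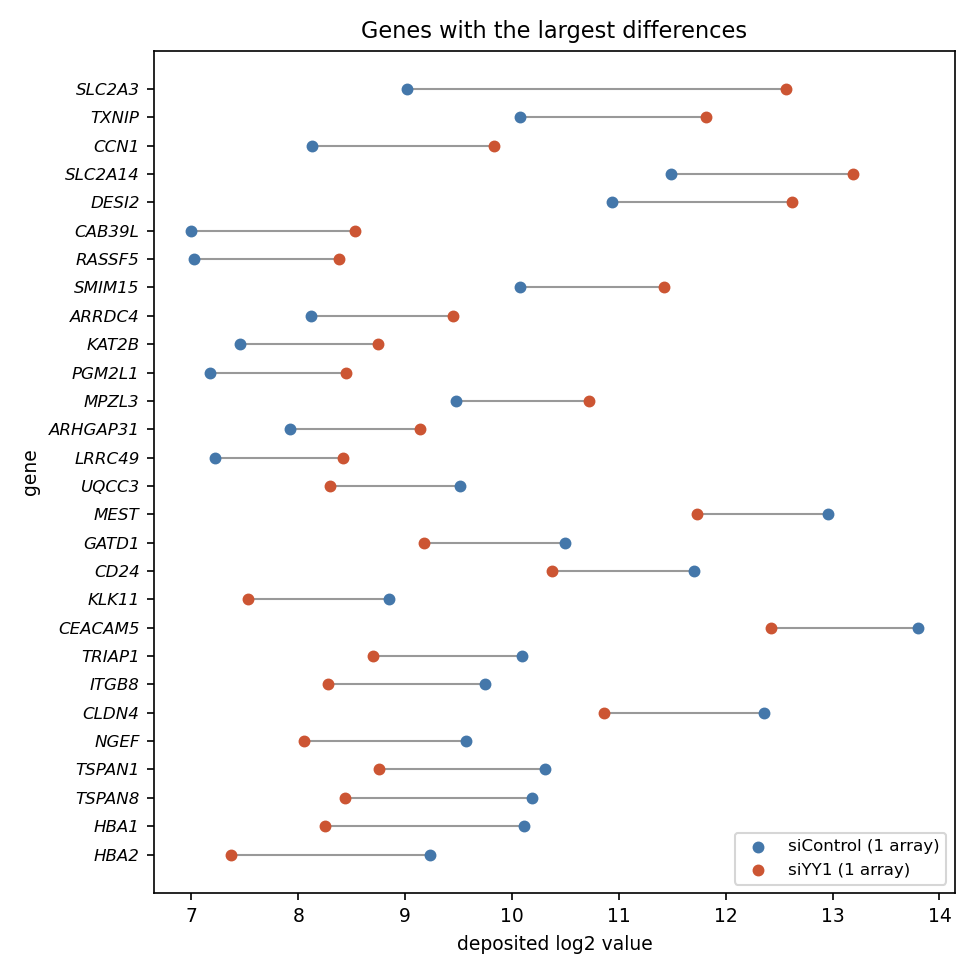
Deposited log2 value (horizontal axis) of the 14 genes with the largest positive and the 14 with the largest negative difference among the genes kept, each gene on its own line. Blue points stand for the siControl array and orange points for the siYY1 array, with 1 array per group and no error bars. SLC2A3 has the widest gap, from 9.02 to 12.56.

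At the threshold of 1.5-fold, 269 genes were higher and 334 lower in siYY1, which made 603 genes or 6.82% of those kept. Olfactory receptor genes, whose expression is mostly restricted to olfactory neurons though some are reported in other tissues, were dim here (median log2 3.92) and gave a rough view of the scatter between the arrays. Of 349 such genes, 37 (10.6%) lay past 1.5-fold and 0 past 2-fold. The largest absolute difference among them was 0.93, and 115 of the genes kept exceeded it. Dim probes scatter more than bright ones, so this bounds the scatter of the kept genes only roughly. The count at 1.5-fold was therefore not above the share seen in genes near the floor. The genes named above were picked as the most extreme of a far larger set, so their lying beyond the olfactory range does not show that they exceed scatter. Of the reference genes, ACTB differed by 0.11 and GAPDH by -0.03, while the list of 13 reference genes had a median of -0.15. GAPDH lay above 16, the log2 ceiling of a 16-bit scanner, on both arrays, so its small difference does not show that it was stable.

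**Figure D2:**
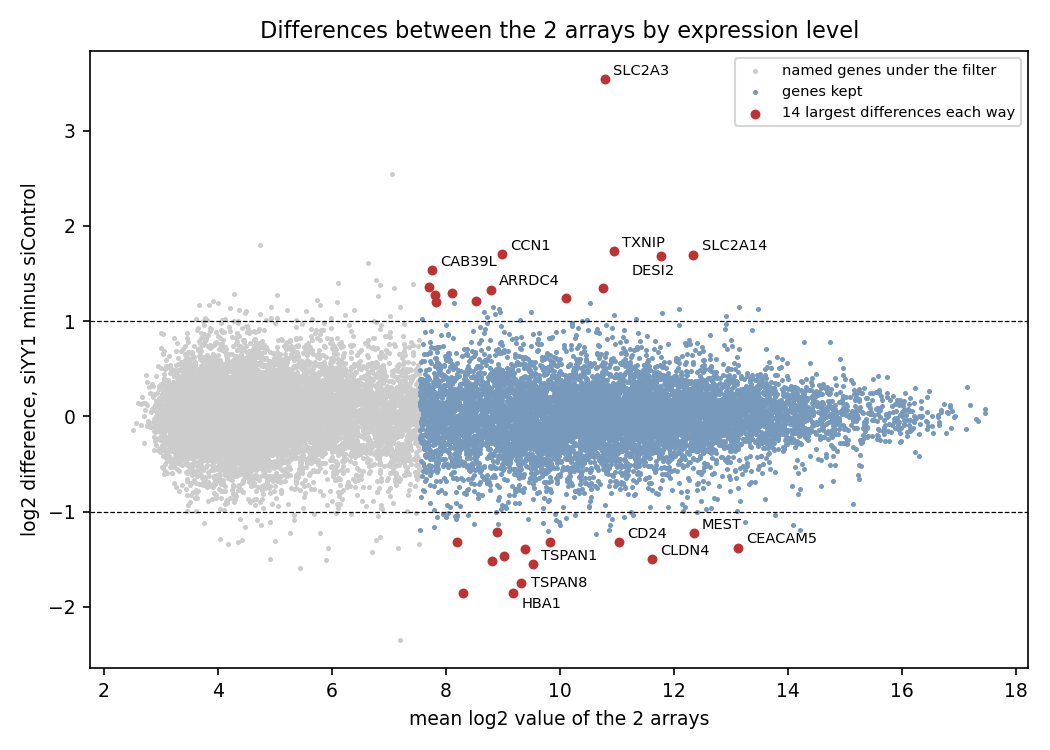
Log2 difference between siYY1 and siControl (vertical axis) against the mean log2 value of both arrays (horizontal axis), with 1 point per named gene. Grey points lie under the expression filter (mean log2 of 7.54), blue points are the 8844 genes kept, red points are the 14 genes with the largest difference in each direction, and dashed lines mark differences of 1 and -1. SLC2A3 lies apart from all other genes kept, with a difference of 3.54.

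Gene lists fixed in advance were then compared with random lists of the same size and matched expression. Of 44 lists with enough genes, 15 lay outside the central 95% of random lists, 9 on the low side and 6 on the high side. About 2.2 lists would do so with independent genes. Genes of cholesterol synthesis, antioxidant defence, DNA replication, ribosomes, respiratory complexes II to V and the tricarboxylic acid cycle were lower in siYY1 as groups, as were the reference genes and 5 enterocyte markers. Genes of the amino acid stress response, transforming growth factor beta (TGF-beta) and bone morphogenetic protein (BMP) signalling, histones, lysosomes and protein folding in the endoplasmic reticulum were higher as groups, as were 5 mesenchymal genes. Most of these shifts were small, and within each list most members lay under 1.5-fold.

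The cholesterol synthesis and uptake genes had the lowest position. Of 20 genes kept, 16 were lower, and the median difference was -0.28 (percentile 0 among random lists). The 3 members at least 1.5-fold lower were INSIG1, a sterol-regulated retention protein (-0.75), the mevalonate pathway kinase PMVK (-0.67) and, named after its value was seen, the synthesis enzyme HSD17B7 (-0.61). No member was 1.5-fold higher, and the largest positive differences were those of SC5D (0.22) and CYP51A1 (0.10). Fatty acid and triglyceride synthesis genes, a related list of 15 genes, had a median of -0.13, inside the range of random lists (percentile 6.56).

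Antioxidant genes regulated by NRF2 had a median of -0.25 over 17 genes (percentile 0.02), with 12 lower and 5 higher. The thioredoxin reductase gene TXNRD1 (-1.04) and OSGIN1 (-0.82) were past 1.5-fold. The cystine transporter gene SLC7A11 (0.30) and GCLM (0.27), a subunit of the enzyme that limits glutathione synthesis, had the largest positive differences. The position of this list was inside the range of random lists when no expression filter was applied (median -0.09, percentile 6.74) and with a stricter filter (median -0.10, percentile 9.37).

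Lists for translation and respiration had small negative medians. The 13 reference genes had a lower median (-0.15, percentile 2.295), so falls of this size were not particular to these lists. Of 44 cytosolic ribosomal protein genes, 38 were lower, with a median of -0.10 (percentile 0.02) and no member past 1.5-fold. Some members lay near or above 16, among them RPL14 (16.14 in siControl and 16.27 in siYY1). The sizes of such differences are uncertain for that reason. The largest negative differences were those of RPL30 and RPS7, each -0.26. Many ribosomal protein genes have processed pseudogenes that probes can share, so single values are uncertain. Mitochondrial ribosomal proteins had the same median of -0.10 over 67 genes (percentile 0.915), with MRPS28 (-1.04) and MRPL21 (-0.59) past 1.5-fold. Nuclear-encoded subunits of respiratory complexes II to V also had a median of -0.10 (37 genes, percentile 0.36). There, COX5A (-0.71), ATP5MC2 (-0.60) and, named after its value was seen, COX7B (-0.59) were past 1.5-fold, while UQCR10 differed by 0.42. Tricarboxylic acid cycle enzymes had a median of -0.14 over 16 genes (percentile 1.76), with SUCLG2 at -0.35. The list of 32 complex I subunits stayed inside the range of random lists (median -0.10, percentile 3.42), and its member NDUFC1 was higher by 0.90. Against random lists that were not matched on expression, complexes II to V (percentile 3.45) and the tricarboxylic acid cycle (percentile 4.70) were inside the range, as was the latter with matching on gene span too (percentile 2.63).

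DNA replication genes were lower as a group, with 33 of 46 genes below 0 and a median of -0.14 (percentile 0.21). The primase subunit genes PRIM2 (-0.75) and PRIM1 (-0.63) were past 1.5-fold, as was the licensing factor gene CDT1 (-0.60), named after its value was seen. E2F1 (0.36) and DSCC1 (0.34) differed in the opposite direction. Replication-dependent histone genes, which are also expressed in S phase, lay on the other side, with 27 of 32 genes above 0 and a median of 0.14 (percentile 99.6). H2BC17 (0.90) and H4C1 (0.65) were the highest. Histone genes are near-identical copies of each other, so their single values are uncertain. If probes are shared, the 32 genes are not separate measurements, and the position of the list among random lists is uncertain too. Genes of G2 and mitosis showed no shift, with a median of 0.01 over 60 genes (percentile 50.7) and no member past 1.5-fold in either direction. Among 12 cyclins, kinases and inhibitors of G1, the median was -0.07, with CDK2 at -0.86 and CCND3 at 0.77.

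Amino acid starvation and integrated stress response genes had a median above those of all 10000 random lists. Of 24 genes, 21 were higher and the median was 0.29 (percentile 100). CHAC1, a glutathione-degrading enzyme, was higher by 0.97, and the stress-induced mTOR inhibitor DDIT4 by 0.91. In all, 6 members were at least 1.5-fold higher and 0 at least 1.5-fold lower. The serine synthesis gene PSAT1 was an exception at -0.51. The unfolded protein response list had a smaller median of 0.12 over 21 genes (percentile 97.8), led by EDEM1 (0.91), which directs misfolded proteins to degradation, and the chaperone gene DNAJB9 (0.61). That list was at the edge of the random lists and came inside their range in 4 alternative settings, lowess centring among them (percentile 97.495). Lysosome and autophagy genes had a median of 0.12 over 31 genes (percentile 98.4), with the autophagosome protein gene MAP1LC3B at 0.73 and the autophagy receptor gene OPTN at 0.59, and with UVRAG (-0.46) and NPC1 (-0.44) lower.

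TGF-beta and BMP signalling outputs were also above all random lists, with 13 of 15 genes higher and a median of 0.32 (percentile 100). PMEPA1, a feedback inhibitor of TGF-beta signalling, was higher by 0.96 and the BMP target ID3 by 0.63, while the receptor gene TGFBR2 differed by -0.28. Of 32 mesenchymal genes on the array, 5 were bright enough to be kept. Their median was 0.44 (percentile 99.7), with the membrane protease gene MMP14 at 1.09 and COL1A2 at 0.45. Of 34 absorptive enterocyte markers, 5 were kept, 3 lower and 2 higher, with a median of -0.33 (percentile 1.63). CEACAM5 (-1.38) and the brush border peptidase gene DPP4 (-1.11) were the lowest, whereas CDX2 differed by 0.16. Without the expression filter the medians of these small lists changed sign, to -0.052 for the mesenchymal genes and 0.018 for the enterocyte markers. The broader list of 25 epithelial junction and keratin genes had a median of -0.09 (percentile 3.58), with CLDN4 the lowest and the desmocollin gene DSC2 the highest (0.80).

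**Figure D3:**
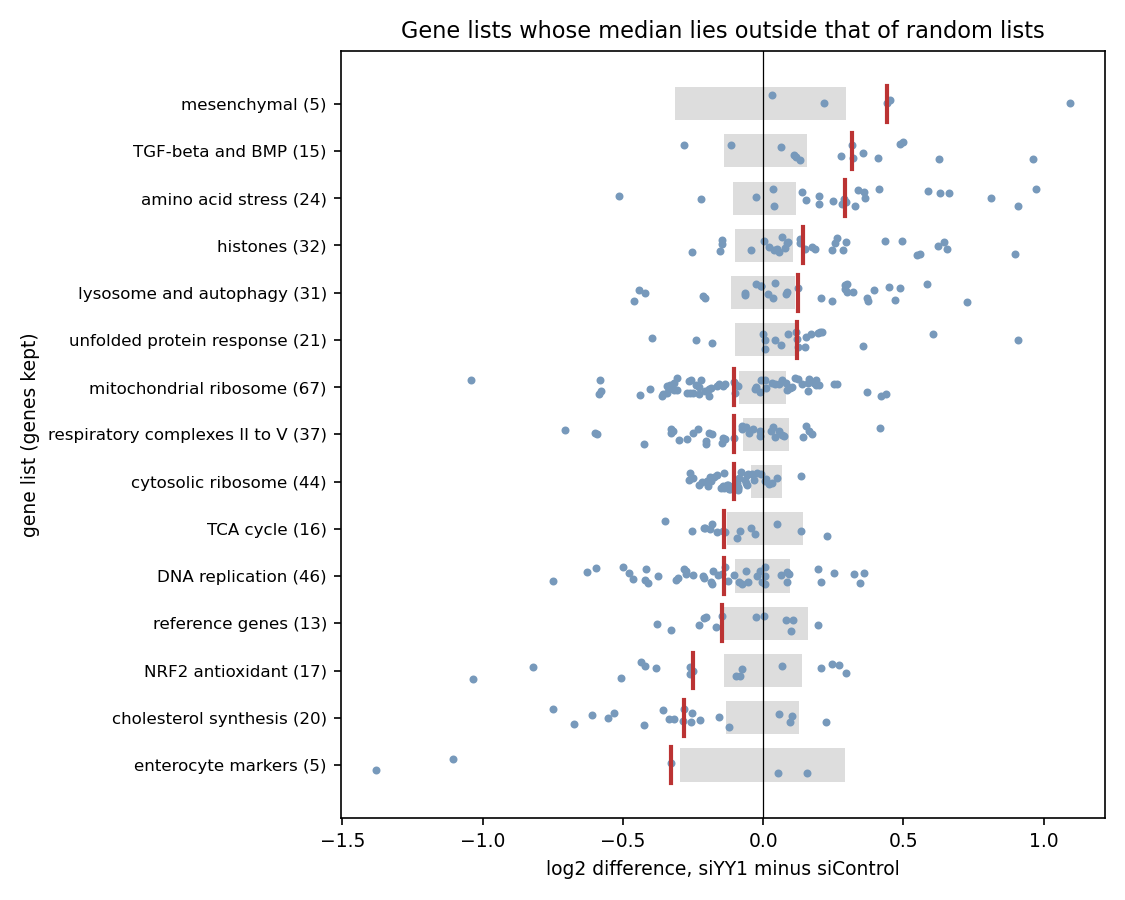
Log2 difference between siYY1 and siControl (horizontal axis) of the genes in the 15 lists that lay outside the central 95% of matched random lists, with the number of genes kept beside each list. Blue points are genes, red lines are list medians, and grey bars span the central 95% of the medians of 10000 random lists. Medians run from -0.33 for enterocyte markers to 0.44 for mesenchymal genes, and both of these lists rest on 5 genes.

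Several lists tied to known roles of YY1 or to colorectal cancer stayed inside the range of random lists. Subunits of the INO80 chromatin remodelling complex, a partner of YY1, had a median of 0.04 over 15 genes, with 0 past 1.5-fold. Polycomb group subunits and YY1 cofactors had a median of -0.02 over 31 genes, with KAT2B at 1.29 and PCGF1 at -0.60. The 7 HOX genes kept had a median of -0.06, with HOXD8 at 0.61. Wnt and beta-catenin target genes had a median of 0.10 over 23 genes (percentile 94.1). Of these, 4 were at least 1.5-fold higher, namely NKD1 (1.09), JAG1 (0.93) and, named after their values were seen, SOX4 (0.71) and TNFRSF19 (0.60). The list of Wnt pathway components had a median of 0.06. The p53 target list had a median of 0.00 over 33 genes, with TRIAP1 lower and SESN2 (0.81) higher. Glucose uptake and glycolysis genes had a median of 0.06 over 24 genes, so the difference of SLC2A3 was not shared by the pathway, in which HK1 differed by 0.52 and ALDOC by -0.74. Hypoxia-inducible genes had a median of 0.04, with EGLN3 at -1.06.

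The signalling lists for YAP and TAZ targets (median 0.20, percentile 96.9), Notch (0.20, percentile 96.7) and NF-kB (0.18, percentile 96.3) lay close to the upper edge, each with 10 genes. Interferon-stimulated genes had a median of 0.08 over 20 genes, with IRF9 at 0.69. Without the expression filter, the lists for YAP and TAZ targets (percentile 98.2), Notch (percentile 99.0) and interferon (percentile 97.6) came outside the range on the high side. Outputs of the ERK pathway had a median of -0.07, with FOSL1 (-0.96) and EREG (-0.64) lower and ETV5 (0.59) higher. The median was 0.10 for apoptosis regulators, in which APAF1 differed by 0.69, and 0.03 for immediate-early genes. It was -0.04 for antigen processing, 0.07 for heat shock proteins, 0.07 for the proteasome and 0.02 for tRNA synthetases. Translation factors had a median of -0.02, the small RNA silencing machinery 0.04, ribosome biogenesis -0.09, DNA repair -0.09 and the spliceosome -0.07, in which EFTUD2 was lower by more than 1.5-fold (-0.71). The 13 reference genes were slightly low, with 8 lower, 5 higher and a median of -0.15 (percentile 2.295). In this list SDHA differed by -0.33. YWHAZ, which lay above 16 on both arrays and is uncertain for that reason, differed by -0.38. The list came inside the range against unmatched random lists (percentile 5.83).

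Most markers of other cell types were dim on both arrays. The median log2 value in siControl was 4.56 for 9 fibroblast markers, 5.37 for 13 leukocyte markers, 4.83 for 8 endothelial markers and 4.89 for 12 hepatocyte and neuron markers. The corresponding medians in siYY1 were 4.60, 5.35, 4.71 and 4.97. The exceptions above the expression filter were the fibroblast marker COL1A2 (8.60 in siControl and 9.05 in siYY1), which is also in the mesenchymal list, and the leukocyte markers CD68 (8.72 and 7.64) and CD79A (7.72 and 7.77), both named after their values were seen. Goblet, Paneth and enteroendocrine markers were also dim, with 1 of 28 genes kept, GFI1, which was named after its value was seen. Mitochondrially encoded genes were not analysed here.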

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

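Probes without a gene name in the annotation used enter no comparison of genes, yet some of them carried a difference between the arrays. Of 1307 such probes above the expression filter, 2 were at least 2-fold higher in siYY1 than in the control array and 9 were at least 2-fold lower. No explanation was tested for these probes, and they are given as counts because their genes were not identified here.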

How the results depend on the processing

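No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out in turn. The count of genes moved by over 1.5 times with the threshold and the filter. It was 33 higher and 51 lower at 2-fold, 1082 and 1192 at a lower threshold (0.32 on the log2 scale), 704 and 690 without the filter, and 87 and 117 with the upper quartile filter. Under quantile normalization, 268 of the 269 higher and 318 of the 334 lower genes remained past 1.5-fold, and under lowess centring 264 and 326. The number of lists on each side stayed within 1.5 times under every alternative run for lists. Without the filter the enterocyte median was 0.018 (percentile 45.4) and the mesenchymal median -0.052 (percentile 11.9), both opposite in sign, as dim members entered the lists. The NRF2 list came inside the range of random lists without the filter and with the upper quartile filter, and the unfolded protein response list in 4 settings, including matching on gene span (percentile 97.385) and lowess centring. The tricarboxylic acid cycle came inside with unmatched random lists and with matching on gene span (percentile 2.63). Complexes II to V and the reference genes (percentile 5.83) came inside with unmatched lists alone. The YAP and TAZ list came outside without the filter and with unmatched lists, and the interferon and Notch lists without the filter. The cause of these changes in counts and lists was not tested. The upper quartile filter left too few genes for the HOX, enterocyte, mesenchymal, Notch, and YAP and TAZ lists. The alternatives planned for the level of YY1 were not run, since that level was not analysed here. Cholesterol, ribosomal, mitochondrial ribosomal, DNA replication, amino acid stress, TGF-beta, histone and lysosome lists stayed outside in every alternative run. Some alternatives were weak checks. Median centring moves lists and random lists alike, so it could not change a percentile. The brightest-probe rule concerned only 20 genes, and quantile normalization acted on arrays that already had nearly the same distribution. Of the named-gene checks under 3 scalings and the brightest probe, 770 kept their side of 1.5-fold, 4 came under it, 2 came past it, and 0 that were past it changed sign. Low signal over background limits dim genes most.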

Other observations

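In this part, lowess centring was planned before the data were examined, but its use as a test of list medians was chosen after its result was seen. Matching on gene span was added after seeing the data, with the test set out before its result was seen. The other tests, and the genes and families first named here, were chosen after their values were seen. Several gene families beyond the fixed lists had members with large differences. Kallikrein-related proteases differed among themselves. KLK10 was lower by 2.28-fold and KLK5, just under the expression filter, went from 8.20 to 6.85, whereas KLK6 differed by -0.46, KLK7 by -0.08 and KLK15 by 0.25. As a family they were inside the range of random lists (median -0.08, percentile 21.1). Among S100 calcium-binding proteins, 8 of 9 kept genes of the S100A group were lower (median -0.21, percentile 1.55), with S100A14 at -1.02, S100A2 at -0.89 and S100A13 at -0.76. In the carcinoembryonic antigen family, the adhesion molecule gene CEACAM1 was lower but dim (6.65 to 5.15), with no measure of background to bound its fold, and CEACAM6 differed by -0.34. Tetraspanins as a family were inside the range of random lists (median -0.14, percentile 8.47), with TSPAN15 at -0.59 and TSPAN13 at 0.15. Single genes outside these families were also lower, among them the urokinase receptor gene PLAUR (-1.14), the membrane serine protease gene TMPRSS4 (-1.20) and EMP1 (-1.11).

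Under the expression filter lay a few large differences, given without folds because the lower values were not shown to be above background. The adaptor complex subunit gene AP4S1 went from 8.37 to 6.02, and the galectin gene LGALS9 from 5.79 to 8.33. The near-identical copies LGALS9C (6.05 to 7.48) and LGALS9B (6.61 to 7.77) were also higher, and probes shared between the copies would leave each value uncertain. CCN3, a relative of CCN1, went from 6.41 to 7.76 and the complement protease gene C1R from 6.73 to 8.12. Genes were also grouped by the stem of their symbol, leaving out the stems LOC, KIAA, FAM and TMEM. The S100A group, which the stem rule does not form, was added after its values were seen. With it, 27 of 284 families lay outside the central 95% of random lists, S100A among them. About 14.2 would do so with independent genes. Families are named here as examples. The largest on the high side was the broad solute carrier stem SLC (181 genes, median 0.07, percentile 99.7), and the lowest percentile was that of mitochondrial ribosomal large subunit genes (MRPL stem, 45 genes, median -0.16, percentile 0.03). The small subunit genes (MRPS stem, 26 genes) were inside the range (median -0.06, percentile 18.9). The MRPL stem and the cytosolic RPL and RPS stems, also low, overlap the fixed ribosomal lists. The count of families is therefore not separate from the count of lists. Also on the high side were 49 RAB genes of vesicle traffic (median 0.12, percentile 99.5) and 6 butyrophilin genes (BTN stem), all above 0 (median 0.27, percentile 97.7). Whether the butyrophilin genes share probes was not checked. Also on the low side were 6 keratins (-0.27, percentile 0.67), 20 nucleoporins (-0.16, percentile 1.22) and 5 SNAPC genes of small nuclear RNA transcription (-0.35, percentile 1.80). The RAB, butyrophilin, keratin, nucleoporin and SNAPC medians kept their sign under quantile, median and lowess scaling. Median centring moved each difference by only 0.00279, so it was a weak check. Quantile and lowess scaling also moved fixed list medians little, as for TGF-beta and BMP outputs (0.318 before, 0.346 and 0.334 after). Family medians of the sizes given here were unlikely to change sign, so these were weak checks too.

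The number of genes past 1.5-fold may be mostly scatter between the arrays, but these arrays cannot show how much of it is. Olfactory receptor genes passed 1.5-fold at 10.6%, against 6.82% of the genes kept. Those genes are dim and dim probes scatter more, so their share cannot decide the question. Among the 1769 brightest genes the share was 3.00% (53 genes). Which single genes differ beyond scatter stays open, since each group had 1 array.

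The lists that stood apart are harder to put down to independent scatter of single genes. When values were shuffled among genes of like expression, at most 8 lists stood apart in 1000 shuffles, with a median of 2, against 15 observed. The shuffles treated all genes as separate measurements, which histone genes that share probes would not be. Cytosolic ribosomal, mitochondrial ribosomal and respiratory complex II to V genes had small negative medians. A trend with intensity over the whole range was argued against as their whole cause. Lowess centring left these medians at -0.117, -0.116 and -0.094, against -0.104, -0.103 and -0.103 before. The fit ran over all named genes, so an effect confined to values near the ceiling of 16 was not addressed. Among the cytosolic ribosomal genes, RPL14 (16.14 in siControl) and RPS7 (15.91 in siControl) lay near it. A trend with gene length was argued against as the whole cause, since 3 of the 3 stayed low against random lists matched on gene span too. Their percentiles were 0.69, 1.31 and 1.56, against 0.02, 0.915 and 0.36 in the main setting. That matching used 5 bins of span and coarser bins of expression. Length differences within a bin were not addressed, and the effects of both changes on the percentiles cannot be separated. Complex I, inside the range of random lists (percentile 3.42), was not part of these tests. Nor were the 13 reference genes, whose median was -0.15 (percentile 2.295), so a wider fall shared with them was not tested. With 1 array per group, a difference between the cultures or hybridisations other than the siRNA cannot be told apart from an effect of the siRNA, and effects of the siRNA on transcripts other than YY1 were not tested.

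Near-identical genes raised the question of shared probes. For HBA1 and HBA2 the gap between the differences was 0, as shared probes would give, with both at -1.86027. Equality to that precision argues against separate measurements of these genes. HBA1 was brighter by 0.88 on both arrays, so the values themselves were not the same. How their probes are shared stays open. For SLC2A3 and SLC2A14 the gap was 1.85, which argues against identical probes for both genes. Partial cross-hybridisation in either direction, or a single transcript read by different probes of both genes, stays open because probe sequences were not used here. No biological explanation was tested.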
